A study of Homo sapiens with 12 samples.

How the data were processed

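RNA from HEK293T cells with stable hairpins was sequenced as stranded poly(A) libraries (TruSeq Stranded mRNA, paired-end reads on a HiSeq X10), per the labels' protocols. Reads were handled with cutadapt 1.18 and HISAT on build GRCh37, per the submitters' processing notes. The HISAT version, the annotation and the versions and settings of MISO and rMATS are not given in the sources used here. The authors deposited 2 tables, named for MISO and rMATS per the file headers. The MISO values are PSI as a fraction from 0 to 1, given by the authors to 2 decimals apart from 54 values with 3, for the control and 6 targets. The rMATS values are the authors' differences in PSI, given to 3 decimals, for 6 targets, with no p-value and no read numbers in the columns used. How the 2 hairpins of a target became 1 column is not stated. Depth is therefore unknown, and no interval on a single PSI is given. For alternative splice sites and mutually exclusive exons the inclusive form is the one that MISO or rMATS defines.

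Groups were taken from the labels. Events with a PSI in all 7 columns entered the main analysis, and each knockdown was compared with scramble and with the mean of the other 5 knockdowns. Before the data were examined, limma across the 12 libraries, a matching test of the hairpins and Fisher's exact test of the gene lists were planned. These need values per library, and with 1 column per target they were not run. Differing was then set by size alone, at 0.1 PSI, the threshold planned for use beside the test, and at 0.2 as an alternative. Also fixed before the data were examined were the 11 gene lists and the rule for named genes: per target the 10 largest higher and the 10 largest lower events, 1 per gene, up to 4 genes per list with a differing event, the events of the PRMT genes, and in the rMATS table the 3 largest per target, type and direction. The condition of that rule on hairpins could not be applied. The text gives a part of the genes so chosen, and 1 of them is not reported here. Events that differed in all 6 knockdowns were chosen after their values were seen.

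The sign of the rMATS table is not stated. Events of both tables were matched by their splice junctions (6525 to 6687 per target). Across matched events, which are not independent replicates, the correlation of the deposited rMATS value with knockdown minus control by MISO was -0.598 to -0.365, so the deposited values were read as control minus knockdown and their sign was turned. The root mean square difference between both tables was 0.0495 to 0.0573 PSI. Gene symbols are those of the table, and 1118 MISO events carry more than 1 symbol, so that a list can count 2 genes for 1 event.

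Shares of events with a lower PSI have 95% exact (Clopper-Pearson) intervals. For the shared control, 100 simulations drew 7 unchanged columns per event from the deviations of the 6 knockdowns from their mean. Gene lists were set against 10000 random lists matched on the number of measured events per gene, as a description of these columns. Known differences were planted in simulated data for PRMT5 against scramble over 10358 events, only in events with a mean PSI in the middle of the scale. Of 50 such events each, 28.0% were called in the planted direction at a planted difference of 0.05, 68.0% at 0.1, 84.0% at 0.2 and 94.0% at 0.3. Of the 10158 events with none, at any mean PSI, 8.10% were called in either direction. False calls among mid-scale events alone were not counted, so these rates come from unlike sets. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were the threshold, a filter on mean PSI between 0.05 and 0.95, a logit scale, missing values and the choice of reference. The reference genome of another build was not used, and 1 emptied line of the MISO table was left out.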

Results

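The data describe alternative splicing in HEK293T cells, an established human embryonic kidney line, after stable lentiviral knockdown of 6 protein arginine methyltransferases (PRMTs), the enzymes that methylate arginine in proteins such as RNA-binding and ribosomal proteins. The study asked how these enzymes bear on RNA splicing. Its labels list 12 poly(A) RNA-seq libraries: 1 with a scramble hairpin, 2 hairpins each for PRMT1, PRMT3, PRMT4, PRMT5 and PRMT7, and 1 hairpin for PRMT6. The deposited values hold 1 column per target, so each value below is the authors' single value, with no SD, no replicate check and no test. Splicing is given as percent spliced in (PSI), the share of transcripts of an event in its inclusive form, on a 0 to 1 scale. The MISO table lists 16199 events, of which 10358 had a PSI in all 7 columns: 6050 cassette exons, 1152 retained introns, 1179 alternative 3' splice sites, 1037 alternative 5' splice sites and 940 mutually exclusive exons. Read depth is unknown. The number of events with a value was 12217 in scramble, 12571 in PRMT1, 12974 in PRMT3, 13748 in PRMT4, 12238 in PRMT5, 14600 in PRMT6 and 12957 in PRMT7. An event is called differing where PSI differed by at least 0.1, a rule of size alone. Coordinates are GRCh37. Transcript levels of the targeted genes were not analysed here, so the depth of each knockdown is not given.

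PRMT3 knockdown had the most differing events by MISO. Retention of an intron of SRSF1, an SR protein and splicing activator (chromosome 17, 56082962 to 56083161), was 0.67 against 0.24 in scramble and 0.15 to 0.36 in the other 5 knockdowns. An intron of HMGN3, a nucleosome-binding protein, stood at 0.59 against 0.18. Exons were skipped more often in ZBTB43, a zinc finger protein (chromosome 9, 129571072 to 129571194, PSI 0.39 against 0.90), in CHD6, a chromatin remodeller (chromosome 20, 40179944 to 40179999, 0.48 against 0.94), in RIPK2, a kinase of innate immune signalling (0.13 against 0.58), and in RNMT, the mRNA cap methyltransferase (0.26 against 0.68). The authors' deposited table of rMATS differences gave -0.479 for the ZBTB43 exon, -0.324 for CHD6, -0.236 for RIPK2 and -0.292 for RNMT, as knockdown minus control. Among chromatin modifiers, an alternative 5' splice site of SMARCC2, a BAF complex subunit, stood at 0.54 against 0.92, and an exon of EZH2, the H3K27 methyltransferase, at 0.32 against 0.10. Introns of splicing and RNA-binding genes went both ways: HNRNPH3 (0.77 against 0.53), RBM25 (0.48 against 0.30), LUC7L3 (0.93 against 0.69) and the helicase gene DDX17 (0.67 against 0.47) were higher and SRSF5 (0.72 against 0.85) lower, and of all 173 differing introns 104 were lower. This SRSF5 intron (chromosome 14, 70235969 to 70236227) stood at 0.67 to 0.76 in the other knockdowns. The SRSF5 intron given below for PRMT5 and PRMT1 is another (70238262 to 70238633). In all, 1087 events in 845 genes differed from scramble, 453 higher and 634 lower, and 726 differed from the mean of the other knockdowns. Of the 20 events with the largest differences, the authors' deposited table held 11, and 10 went the same way there. Against the other knockdowns, the authors' deposited table had more differing events in PRMT6 (6455) than in PRMT3 knockdown (5282).

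PRMT5 knockdown stood out by higher exon inclusion. The exon of FAM126A, a component of a phosphatidylinositol 4-kinase complex (chromosome 7, 22986571 to 22986866), had a PSI of 0.84 against 0.37 in scramble and 0.44 to 0.64 in the other knockdowns. Inclusion was also higher in OBSL1, a cytoskeletal adaptor (0.56 against 0.14), TUSC3, an oligosaccharyltransferase subunit (0.72 against 0.30), DZIP1L (0.90 against 0.56), NIN, a centrosomal protein (0.69 against 0.35), and BPTF, the large subunit of the NURF remodeller (0.93 against 0.59). Differences in the authors' deposited table were 0.378 for FAM126A, 0.258 for OBSL1, 0.057 for TUSC3, 0.267 for DZIP1L, 0.204 for NIN and 0.142 for BPTF. By MISO the other knockdowns reached 0.36 for OBSL1, 0.48 for TUSC3 and 0.65 for DZIP1L, but 0.61 for NIN and 0.90 for BPTF. The authors' deposited table gave 0.208 for NIN in PRMT6 knockdown, and 0.206 for BPTF and 0.252 for FAM126A in PRMT7 knockdown. The exons of NIN, BPTF and FAM126A are thus not particular to PRMT5. An exon of RAD51AP1, a homologous recombination factor, stood at 0.86 against 0.43 by MISO, but the authors' deposited table gave -0.015 for it. Among RNA-binding genes, HNRNPC showed more use of an alternative 3' splice site (0.92 against 0.61), and introns of SRSF5 (0.23 against 0.50) and QKI (0.67 against 0.92) were retained less. Another event over the same QKI intron stood at 0.34 in scramble and 0.25 to 0.45 in the knockdowns other than PRMT1. Exons of MPZL1 (0.14 against 0.42) and FHL2 (0.22 against 0.50) were included less. The other knockdowns spanned 0.20 to 0.50 for MPZL1 and 0.20 to 0.63 for FHL2, so the lower FHL2 exon is not particular to PRMT5. In all, 857 events in 690 genes differed from scramble, 473 higher and 384 lower, and 620 differed from the other knockdowns. Of the 15 of the 20 largest held by the authors' deposited table, 13 went the same way.

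PRMT1 knockdown, which targets a major asymmetric dimethyltransferase, had 767 differing events in 627 genes, 310 higher and 457 lower. Inclusion was higher for exons of DSC2, a desmosomal cadherin (0.67 against 0.40), ANK2, an ankyrin (0.75 against 0.48), and KDM6A, an H3K27 demethylase (0.60 against 0.29). The other knockdowns spanned 0.30 to 0.66 for DSC2, 0.49 to 0.74 for ANK2 and 0.42 to 0.50 for KDM6A. Higher inclusion of the DSC2 and ANK2 exons is thus not particular to PRMT1. Retention of an intron of RELL2 (chromosome 5, 141017309 to 141017736) was 0.30 against 0.67, and an alternative 5' splice site of RBBP5, a subunit of H3K4 methyltransferase complexes, stood at 0.56 against 0.89. The authors' deposited table gave 0.142 for DSC2, 0.194 for ANK2, 0.083 for KDM6A, -0.261 for RELL2 and -0.108 for RBBP5. Introns of SRSF5 (0.24 against 0.50), HNRNPH1 (0.21 against 0.39) and EWSR1 (0.73 against 0.88) were retained less. An intron of QKI stood higher (0.48 against 0.34), but another event over the same intron went the other way. There scramble stood at 0.92 and the knockdowns other than PRMT5 at 0.78 to 0.90. Set against the other knockdowns, 381 events differed. Of the 20 largest, 10 of the 12 held by the authors' deposited table went the same way.

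PRMT4 (CARM1) knockdown had 774 differing events in 633 genes, 335 higher and 439 lower. By MISO, an event of SLC22A5, a carnitine transporter, stood at 0.20 against 0.95. It is listed as a cassette exon, but its alternative part is 5924 bases long (chromosome 5, 131714070 to 131719993). The same event was low in PRMT1 (0.38), PRMT6 (0.43) and PRMT3 (0.49) knockdown too, and it was not matched in the authors' deposited table. An alternative 5' splice site of AKT1S1, an mTORC1 component, stood at 0.29 against 0.84. Exons of HYAL2 and of NUMB, a Notch regulator, stood at 0.62 against 0.10 and at 0.95 against 0.46. The authors' deposited table held 8 of its 20 largest differences, of which 3 went the same way. Values in the authors' deposited table were 0.097 for an exon of ZNF598 (0.95 against 0.56 by MISO), only 0.017 for NUMB, and -0.021 for an exon of BOD1 that MISO put at 0.90 against 0.39. Smaller MISO differences went the same way in both for an intron of CENPT, a kinetochore protein (0.47 against 0.64, -0.098 in the authors' deposited table), and an exon of MBNL1, a splicing regulator (0.66 against 0.81, -0.113 in the authors' deposited table). A comparison with the other knockdowns gave 400 differing events.

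PRMT6 knockdown, with a single hairpin in the labels, had 708 differing events in 576 genes, 259 higher and 449 lower. An exon of CREBZF, a bZIP factor, stood at 0.60 against 0.18 and an exon of CNOT4, a ubiquitin ligase tied to the CCR4-NOT complex, at 0.62 against 0.37. Introns were retained less in DDX39B, an RNA helicase of splicing and mRNA export (0.46 against 0.74), NFATC4 (0.37 against 0.64) and AURKB, a mitotic kinase (0.21 against 0.51). Exons of FAHD2A (0.17 against 0.50) and MKNK1, a kinase that phosphorylates eIF4E (0.51 against 0.79), were included less. The authors' deposited table gave 0.277 for CREBZF, 0.159 for CNOT4, -0.133 for DDX39B, -0.258 for NFATC4, -0.348 for FAHD2A and -0.143 for MKNK1. Compared with the other knockdowns, 465 events differed. Among the 20 largest, 9 of the 10 held by the authors' deposited table went the same way.

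PRMT7 knockdown had the fewest events that differed by at least 0.1, 657 in 533 genes, 263 higher and 394 lower. An exon of TRA2A, a splicing activator, stood at 0.46 against 0.20, and an exon of EEF1D, a translation elongation factor subunit, at 0.27 against 0.06. An alternative 3' splice site of BAHD1, a heterochromatin protein, stood at 0.55 against 0.83, and exons of MPPE1 (0.32 against 0.64) and ZNF655 (0.25 against 0.53) were included less. Values in the authors' deposited table were 0.112 for TRA2A, 0.238 for EEF1D, -0.244 for BAHD1, -0.145 for MPPE1 and -0.12 for ZNF655. The MPPE1 exon was low in PRMT5 (0.33) and PRMT1 (0.35) knockdown too, at -0.225 and -0.092 in the authors' deposited table. Against the other knockdowns 312 events differed. Among its 20 largest, 11 of the 12 held by the authors' deposited table went the same way.

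**Figure D1:**
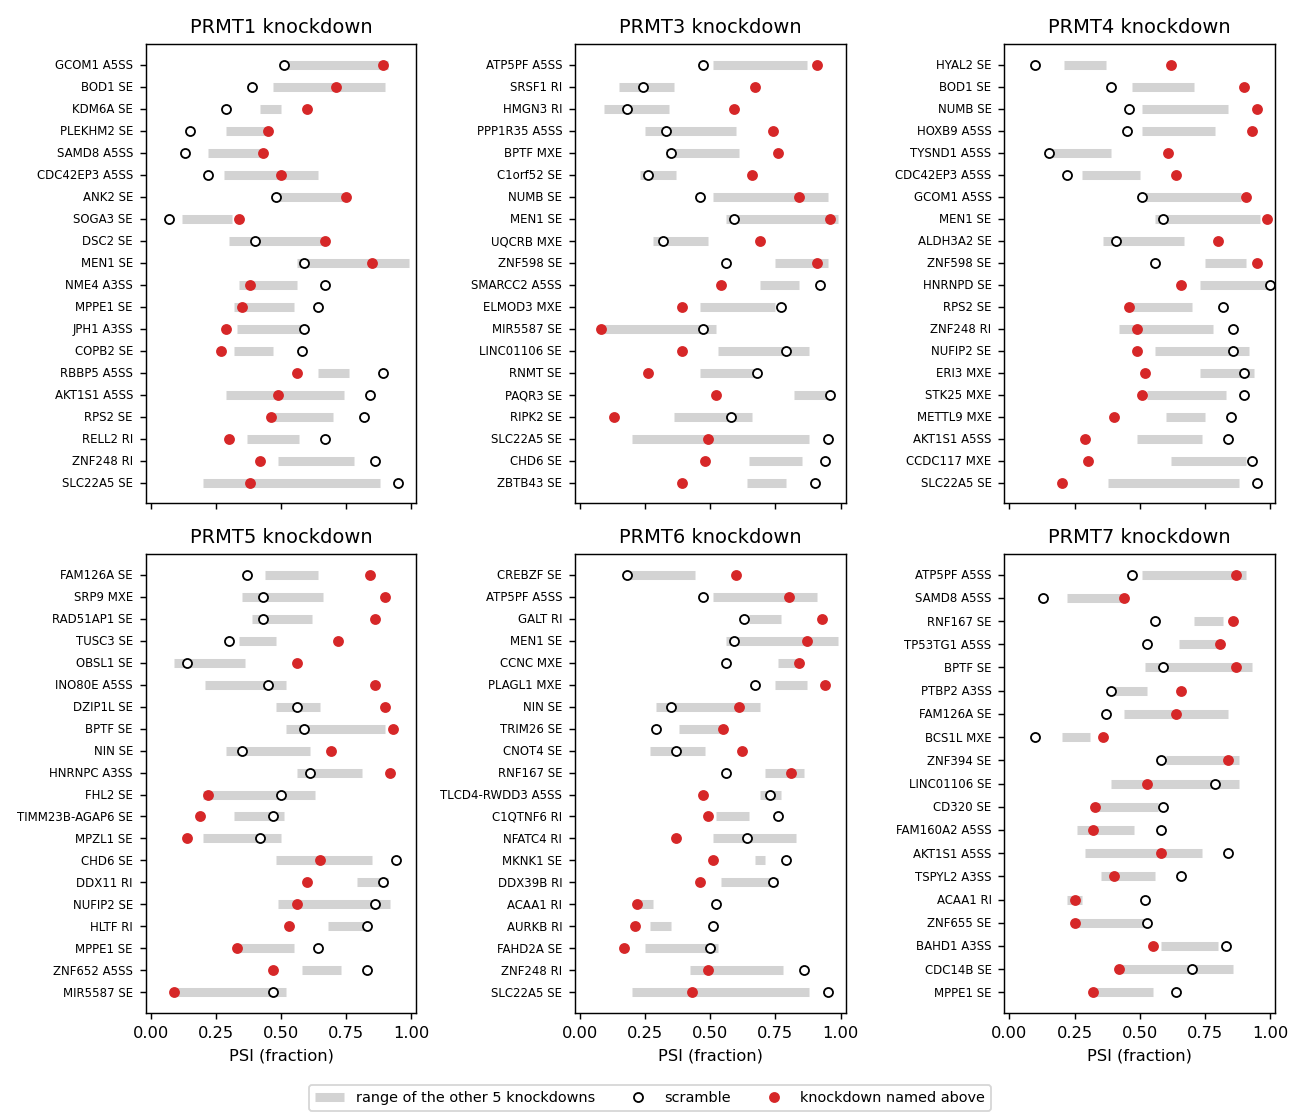
Deposited PSI (x axis, fraction) of up to 10 events with the largest higher and up to 10 with the largest lower PSI per knockdown against scramble, 1 event per gene, labelled by gene (the symbol listed at the start of each entry) and event type: SE, cassette exon, RI, retained intron, A3SS and A5SS, alternative 3' and 5' splice sites, MXE, mutually exclusive exons. Open circles are scramble, red circles the knockdown, grey bars the range of the other 5 knockdowns. SRSF1 under PRMT3 stood at 0.67, outside the range of 0.15 to 0.36 of the others.

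Direction differed between event types and targets. Cassette exons in PRMT5 knockdown were mostly more included: 280 were higher and 153 lower, so that 35.3% were lower (95% exact binomial interval 30.8 to 40.0), and 26.5% (21.7 to 31.7) against the other knockdowns. The authors' deposited table gave 4016 higher and 2353 lower cassette exons for PRMT5. In PRMT3 knockdown 60.5% of differing cassette exons were lower (56.3 to 64.6), and in PRMT7 knockdown 59.2% (53.8 to 64.5), whereas in the authors' deposited table these shares were 49.0% and 44.2%. Against the other knockdowns they were 66.9% and 64.3% by MISO, and 57.9% (56.4 to 59.4) and 50.6% (48.7 to 52.6) in the authors' deposited table. For PRMT1, PRMT4 and PRMT6 the shares were 53.2%, 45.5% and 53.7%, with intervals that include 50%, but in the authors' deposited table the shares were 44.4% in PRMT1 (43.1 to 45.7), 46.0% in PRMT4 (44.7 to 47.2) and 49.1% in PRMT6 (47.9 to 50.3). By MISO against the other knockdowns, PRMT4 had 40.1% lower (33.4 to 47.1), but in the authors' deposited table the share was 52.6% (50.8 to 54.3). Retained introns were mostly lower than in scramble in all 6 knockdowns: 82.5% of differing introns in PRMT1, 60.1% in PRMT3, 83.8% in PRMT4, 69.7% in PRMT5, 89.0% in PRMT6 and 67.3% in PRMT7. Set against the mean of the other knockdowns, the shares were 38.9% in PRMT3, 35.7% in PRMT5, 24.0% in PRMT7, 67.3% in PRMT1, 66.7% in PRMT4 and 76.6% in PRMT6. Such deviations sum to 0 for each event, so shares on both sides of 50% follow from the comparison, which ranks the knockdowns and does not test the difference from scramble. In the authors' deposited table, set against the other knockdowns in the same way, introns were mostly lower in PRMT4 (71.3%) and PRMT6 (64.4%) but not in PRMT1 (43.8%). The mean PSI of retained introns was 0.529 in scramble, 0.511 in PRMT1, 0.523 in PRMT3, 0.510 in PRMT4, 0.518 in PRMT5, 0.504 in PRMT6 and 0.520 in PRMT7. The intervals cover the counting of events only, not the spread between cultures, and events of a gene are not independent.

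**Figure D2:**
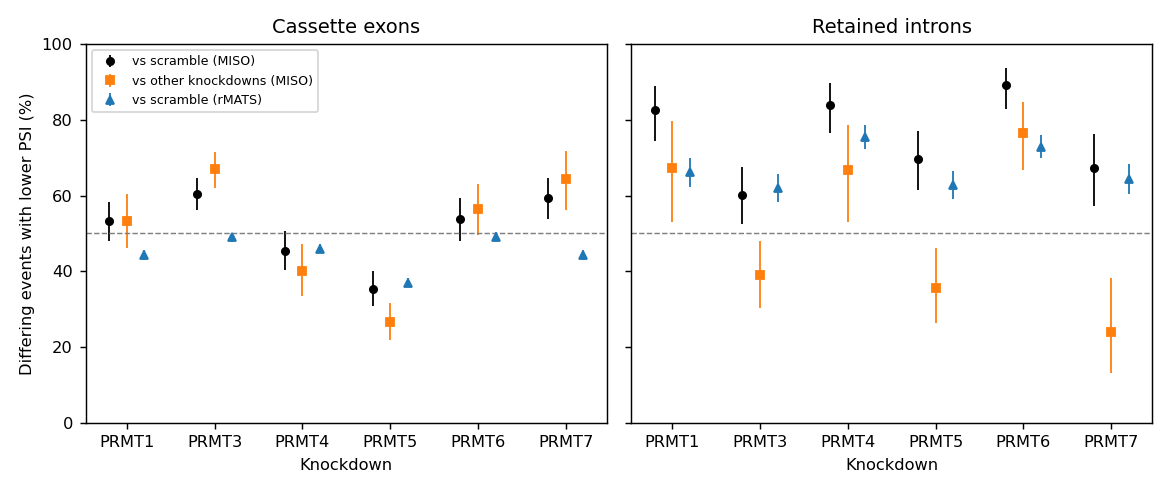
Share of differing events with a lower PSI (y axis, percent) for cassette exons and retained introns in each knockdown. Points are shares against scramble in the MISO table, against the other knockdowns in the MISO table, and against scramble in the authors' deposited table of rMATS differences, with 95% exact binomial intervals that cover counting only. Cassette exons under PRMT5 lie below 50% in all 3, at 35.3%, 26.5% and 36.9%.

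Some events differed from scramble in the same direction in all 6 knockdowns: 16 were higher and 42 lower. Retention of an intron of ACAA1, a peroxisomal thiolase (chromosome 3, 38167833 to 38168000), was 0.52 in scramble and 0.22 to 0.28 in the knockdowns. An intron of AURKB stood at 0.51 and 0.21 to 0.35, and an intron of VIM, the intermediate filament protein vimentin, at 0.66 and 0.36 to 0.47. Exons of KIF13A, a kinesin (0.57 and 0.23 to 0.40), and CLIP1, a microtubule plus-end protein (0.34 and 0.04 to 0.20), were lower, and exons of PLEKHM2, a lysosome-kinesin adaptor (0.15 and 0.29 to 0.45), NAB2, a corepressor (0.54 and 0.74 to 0.87), and KDM6A (0.29 and 0.42 to 0.60) were higher. The authors' deposited table held 34 of the 58 events, and 29 of them were on the same side in all 6 targets there. The exceptions in the authors' deposited table were TGOLN2 and RNF167 (same side in 0 targets), CFLAR (3), RPS2 (4) and ATXN2L (5). The labels list a single scramble library, and the sign of the rMATS values was set from MISO differences. The count of 29 is therefore no independent check. Mean differences in the authors' deposited table were -0.164 for KIF13A, -0.143 for CLIP1, 0.173 for NAB2 and 0.127 for PLEKHM2, but only -0.0432 for ACAA1, -0.00967 for VIM and 0.0703 for KDM6A. Several events given under single targets also belong here: AKT1S1 (0.84 and 0.29 to 0.74), HYAL2 (0.10 and 0.21 to 0.62), ZNF598 (0.56 and 0.75 to 0.95), ZBTB43 (0.90 and 0.39 to 0.79), RELL2 (0.67 and 0.30 to 0.57), RBBP5 (0.89 and 0.56 to 0.76) and the RPS2 exon (0.82 and 0.46 to 0.70). The lower group held 15 cassette exons and 14 retained introns. These comparisons share the scramble library, so its own deviation enters all of them. Unchanged groups were simulated with all spread between the knockdowns taken as noise, real differences included, which gave 68.4 such events on average (48 to 86 over 100 simulations). The same simulations gave 841 differing events for a single target on average (770 to 919). The PRMT3 count (1087) lay above that range, PRMT4 (774) and PRMT5 (857) inside it, and PRMT1 (767), PRMT6 (708) and PRMT7 (657) below it. The simulations draw each event by itself, so their ranges are narrow. Of the 20 largest differences of each target, 12 to 20 lay at least 0.1 beyond the mean of the other knockdowns in the same direction, but so did 16.6 of 20 on average for a simulated target without change (10 to 20), so this does not set them apart from noise in a single column.

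For couples of knockdowns, the Jaccard index of differing events had a median of 0.250 (0.202 to 0.304), against 0.308 in the simulation. PRMT1 and PRMT4 shared 359 events, 97.2% in the same direction, and PRMT5 and PRMT6 shared 263, 80.6% in the same direction. A simulated couple that shares the control and has no change shared 396 on average (339 to 453), 93.8% in the same direction (88.3 to 97.5). The correlation of PSI differences across events, which are not independent replicates, had a median of 0.470 (0.297 to 0.635), against 0.500 simulated (0.451 to 0.553 for a single couple), and the mean covariance was 0.00135, against 0.00155. With a single scramble library the control could not be split, and by MISO the median overlap was no larger than sharing it gives in the simulation. The authors' deposited table had a median Jaccard index of 0.476, for which no simulation was run. Without the control, PRMT1, PRMT4 and PRMT6 lay closest together: 608 events differed between PRMT1 and PRMT4, 609 between PRMT4 and PRMT6 and 633 between PRMT1 and PRMT6, whereas 1138 differed between PRMT3 and PRMT6. On the matched events of the authors' deposited table PRMT1 stayed close to PRMT4 (194) and PRMT6 (191), but PRMT4 and PRMT6 lay farther apart (318), and the closest couple was PRMT1 and PRMT7 (115). Over all events of the authors' deposited table PRMT1 and PRMT7 were again closest (4992), with 5645 between PRMT1 and PRMT4, 6352 between PRMT1 and PRMT6 and 7385 between PRMT4 and PRMT6.

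**Figure D3:**
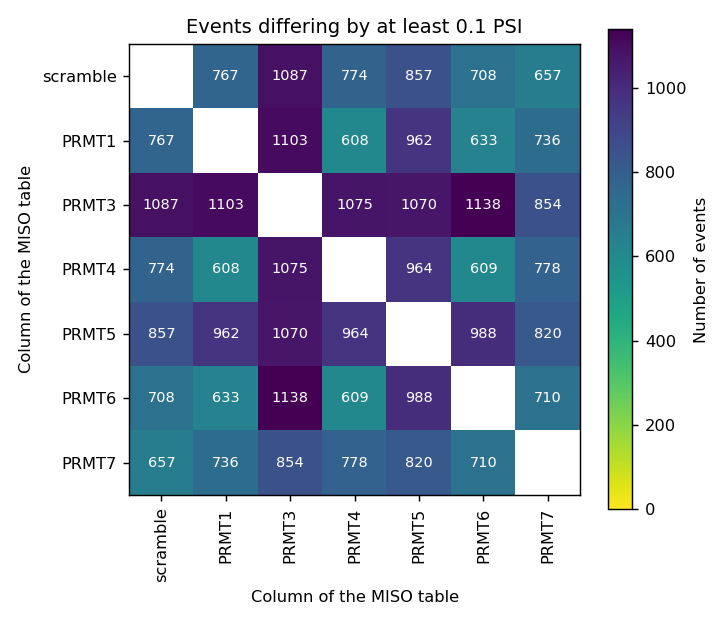
Number of events (colour and printed value) whose PSI differed by at least 0.1 between each couple of columns of the MISO table, over 10358 events. PRMT3 differs from every other column by at least 854 events, and the lowest value is 608, between PRMT1 and PRMT4.

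Genes were grouped by 11 lists. Translation factors and ribosomal proteins had few differing events: of 86 genes measured, 8 had 1 in PRMT1 knockdown and 13 in PRMT3 knockdown, at percentiles of 1.56 to 6.56 over the 6 knockdowns among 10000 random lists with as many measured events per gene. These 6 comparisons share the scramble library, so their likeness is not independent support. Against the other knockdowns the percentiles ran from 3.6 in PRMT3 to 38.6 in PRMT7. Examples were an intron of RPS9, 0.31 in PRMT3 knockdown against 0.58, and an exon of RPS2, 0.46 in PRMT1 knockdown against 0.82, for which the authors' deposited table gave -0.011. Of 44 core spliceosome genes, 1 to 5 had a differing event (percentiles 0.895 to 18.7), such as an alternative 3' splice site of SF1 in PRMT3 knockdown (0.64 against 0.94). Chromatin modifiers stood at the other end, with 14 to 19 of 76 genes (78.8 to 98.1), among them INO80E (0.86 against 0.45) and CHD9 (0.53 against 0.79) in PRMT5 knockdown. Among 20 SR proteins and their kinases, 2 to 6 genes had a differing event (17.0 to 87.9), and among 37 hnRNPs and other splicing regulators 5 to 12 (23.9 to 86.3), including HNRNPD, 0.56 in PRMT3 knockdown against 0.87. Counts were 3 to 5 of 27 RNA helicases (20.9 to 64.0), 3 to 8 of 36 genes of 3' end processing and decay (21 to 82.5), 5 to 11 of 60 DNA repair genes (11.2 to 56.6), 10 to 16 of 63 cell cycle genes (55.9 to 89.4), 4 to 9 of 24 apoptosis genes (41.1 to 95.7) and 0 to 1 of 6 PRMT family members and partners (19.2 to 64.7). Of 66 list and target combinations, 2 lay above the 97.5th percentile and 3 below the 2.5th, where chance gives 1.65 each. None of these 5 lay beyond those percentiles against the other knockdowns, where hnRNPs in PRMT3 and PRMT7 knockdown and SR proteins in PRMT1 knockdown did (98.8, 97.9 and 98.5).

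Splicing of the PRMT genes themselves was measured in 14 events, including those of partner genes. An exon of PRMT9 (chromosome 4, 148601474 to 148601622) had a PSI of 0.75 in PRMT3 knockdown against 0.93 in scramble, and an exon of PRMT2 (chromosome 21, 48083295 to 48083466) stood at 0.80 in PRMT1 and 0.81 in PRMT6 knockdown against 0.95. The measured events of PRMT5 lay within 0.05 of scramble in every knockdown.

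The authors' deposited table of rMATS differences covers more events, 60623 with a value for all 6 targets. Differing events there, in the authors' deposited table, numbered 7594 for PRMT1, 9284 for PRMT3, 8336 for PRMT4, 8376 for PRMT5, 9128 for PRMT6 and 7528 for PRMT7. Its largest differences were at the end of the scale: of 144 events chosen by size per target and type, 99 had a difference of 1 in either direction, such events were 93 to 158 per target, and 1 to 3 per target were also in the MISO table. Below that, the authors' deposited table gave an intron of BEST1 at 0.931 for PRMT1, PRMT5 and PRMT6, and an intron of NLRC5 at -0.934 for PRMT3. Of the MISO events that differed and were in both tables, 79.9 to 90.7% per target had the same direction in the authors' deposited table, but 20.8 to 39.1% reached 0.1 there. The sign of that table was set once for all targets from its correlation with these MISO differences, so shares above 50% follow from that step and are no independent check.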

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

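No paired analysis was possible because each target has 1 column, the hairpins are not given separately and the control has no hairpin number. For the same reason the fits without 1 hairpin, the hairpin block, another variance prior and the planned correlation of hairpins were not run, and the planned overlap without a test is the one reported. The settings for events above 0.10, support by rMATS, the median of the others, the others without PRMT3, matched rMATS events and both overlap settings were chosen after seeing the data, as was the threshold of the logit scale (0.401, the step from 0.45 to 0.55). Values in 6 of 7 columns stood in for the planned 10 of 12 libraries. Counts stayed within 1.5 times with the filter on mean PSI, values in at least 6 of 7 columns, strictly above 0.10, the median of the others and the others without PRMT3. Unless said otherwise the cause of a shift was not tested. Targets follow in the order PRMT1, PRMT3, PRMT4, PRMT5, PRMT6 and PRMT7.

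A threshold of 0.2, stricter by construction, left 111, 260, 147, 135, 90 and 97 events against scramble, 23, 142, 49, 96, 45 and 18 against the other knockdowns, and 3220, 3892, 3427, 3538, 3944 and 3173 in the authors' deposited table. On the logit scale, where steps of 0.01 near 0 and 1 pass the threshold, 4486, 5166, 4781, 4676, 4738 and 4409 events differed from scramble and 3382, 4101, 3436, 3937, 3585 and 3136 from the other knockdowns. Asking for 0.1 in the authors' deposited table too left 99, 260, 107, 148, 148 and 90. Restricted to events matched to MISO, the authors' deposited table had 218, 445, 292, 305, 313 and 214.

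The share of lower cassette exons at 0.2 was 30.0% for PRMT5. Against the other knockdowns it was 66.9% for PRMT3, 40.1% for PRMT4 and 26.5% for PRMT5, where the authors' deposited table gave 57.9%, 52.6% and 37.5%, so that PRMT4 went the other way there. For retained introns, the share at 0.2 was 93.3% for PRMT1, 94.7% for PRMT4, 93.8% for PRMT5 and 80.0% for PRMT7. Against the other knockdowns it was 67.3% for PRMT1, 66.7% for PRMT4 and 76.6% for PRMT6, and it reversed to 38.9% for PRMT3, 35.7% for PRMT5 and 24.0% for PRMT7, which follows in part from construction, since deviations from the mean of the others sum to 0 for each event. The median Jaccard index was 0.134 at 0.2 and 0.476 in the authors' deposited table. Against the other knockdowns, the percentiles of lists were 12.1 for core spliceosome in PRMT7, 7.94 and 11 for translation in PRMT1 and PRMT4, and 91.2 and 66.9 for chromatin modifiers in PRMT5 and PRMT6.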

Other observations

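The comparison of PRMT5 exons with the other knockdowns was planned, and the count of 1 event per gene was chosen before its result was seen. The other tests in this part, and the use of that comparison to weigh the shared control, were chosen after the result was seen. So was the condition that a relation with depth must hold without the 2 columns farthest from the median, and without that condition the depth test would have spoken against depth for PRMT5 exons and in favour of depth for introns.

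Among apoptosis genes, an alternative 3' splice site of BCL2L1 stood at 0.08 in PRMT3 knockdown against 0.28 in scramble. It stood at 0.11 in both PRMT1 and PRMT7 knockdown. Another event at that site did not bear out these lower values. There scramble stood at 0.24, PRMT4 knockdown at 0.37 and the other knockdowns at 0.23 to 0.33. An exon of DAXX stood at 0.91 in PRMT5 and 0.85 in PRMT7 knockdown against 0.61. In mitotic genes, an exon of KIF23, a kinesin of cytokinesis, stood at 0.69 in PRMT3, 0.64 in PRMT5 and 0.60 in PRMT7 knockdown against 0.44, and an exon of ANAPC10 at 0.09 to 0.19 over the 6 knockdowns against 0.27. Exons whose length is a multiple of 3 made up 45.0% of those higher in PRMT5 knockdown (39.1 to 51.0) and 41.2% of those lower (33.3 to 49.4), against 41.5% of exons that differed by less.

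Higher exon inclusion in PRMT5 knockdown was weighed against 3 technical explanations. The scramble library is argued against only for the higher inclusion relative to the other knockdowns, a comparison it does not enter. There 26.5% of differing exons were lower (21.7 to 31.7), and 37.5% in the authors' deposited table treated the same way. That comparison ranks the knockdowns and does not test the difference from scramble. By MISO it also gave 66.9% for PRMT3, 64.3% for PRMT7 and 40.1% for PRMT4, so a deviation of the single PRMT5 column is not excluded. Several events of a few genes are argued against by their spread, since the 433 differing exons lay in 387 genes. With 1 event per gene 35.4% were lower (30.6 to 40.4), but so few events drop out that this count could hardly change and adds little. Depth, read from the number of events with a value, stays open: over the 6 columns other than PRMT5 its relation to mean exon PSI had Pearson's r = 0.426 (exact permutation p = 0.392) and Spearman's rho = 0.371 (exact permutation p = 0.497), but r = -0.843 without PRMT4 and PRMT6, so the relation rests on those columns. PRMT5 and scramble differed at nearly the same number of events with a value (12238 and 12217), but PRMT5 has 2 libraries in the labels and scramble 1, so equal numbers need not mean equal depth, and a PRMT5 effect is a hypothesis beside it.

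Lower intron retention than scramble in all 6 knockdowns stays open between the scramble library and the knockdowns. If the scramble library held more intronic signal, introns with small differences should lean the same way: the share lower was above 50% with its interval in 11 of 12 sets, and 49.9% in PRMT3 by MISO. With depth, mean intron PSI over the 7 columns had r = -0.761 (exact permutation p = 0.0409, adjusted by Benjamini-Hochberg over 5 event types 0.204) and rho = -0.679 (exact permutation p = 0.110, adjusted 0.274). Without PRMT4 and PRMT6, the columns farthest from the median, r was -0.115, so the relation rests on these columns. With a single control, neither can be told apart from an effect of the knockdowns, which was not tested. Among the other event types, alternative 3' splice sites had rho = -0.893 with the number of events with a value (exact permutation p = 0.0123, adjusted by Benjamini-Hochberg 0.0615). Their Pearson's r was -0.620 (exact permutation p = 0.140), and -0.938 without PRMT4 and PRMT6.

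By MISO, PRMT3 stood farthest from the median of the other columns (782 events, against 436 for scramble), but in the authors' deposited table scramble did (7011, against 6270 for PRMT6 and 5359 for PRMT3). Events held only by the rMATS table may account for this: on the 6192 events in both, the ratio of scramble to PRMT3 went from 1.31 to 0.688. Whether columns of 1 library vary more stays open with 7 columns: PRMT6, the other such column, came next, which chance gives with a probability of 0.167 once scramble is farthest. On the shared events PRMT6 was 2nd with 215 and scramble had 181, against 263 for PRMT3. No biological explanation was tested.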
